A study of Drosophila melanogaster with 2 samples.

How the data were processed

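The series holds ChIP-seq of C-terminally GFP-tagged tHMG1 from whole adult male flies, in 2 biological replicates (numbers 1 and 3 in the labels) that form 1 group. Per the labels, chromatin was fragmented by sonication, and a separate control experiment is named as a possible control; it was not used here. The deposited data are 8 peak lists, 1 per replicate, 1 of the replicates pooled and 1 that passed the authors' IDR procedure, each for builds dm6 and dm3. Aligner, peak caller, read filters and the IDR threshold are not given in the sources used here.

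Each peak carries a signal as the authors deposited it, which is the caller's own enrichment value and was not scaled between replicates. It was used to describe and rank peaks within a list. Each peak also carries a −log10 q value as the authors deposited it, which reached a single highest value in all IDR peaks and was therefore not used for ranking. The unthresholded dm6 lists hold 30000 peaks each and include background. All 4574 rows of the dm6 IDR list are the 4574 strongest rows of the pooled list, so the IDR list was called on pooled replicates. It repeats 36 intervals with different summits. Peaks of replicate 1 had a median length of 424 bp and those of replicate 3 and the pooled list 444 bp. Because no read counts were used, depth per sample is unknown, no interval for the counting of reads can be given, and binomial intervals refer to numbers of peaks or genes only.

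Genes and TSSs were those of the Ensembl annotation, release 115, without transposable elements (18277 genes), and sequence was that of the release 6 assembly with soft-masked repeats. The last dm6 peak of every arm lay within the length of that arm. A promoter peak had its summit within 500 bp of any annotated TSS, and a gene was bound if a summit lay within 500 bp of 1 of its TSSs. Older symbols in the lists were matched through RefSeq synonyms and a short table of aliases, after which no listed symbol was missing.

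The 28 gene lists, the 12 motifs, the tests and the rule for named genes were fixed before the data were examined. Named are tHMG1 and tHMG2, the genes nearest the 10 strongest peaks and the strongest of each arm, up to 8 bound members of each testis list, up to 4 bound members by signal of every other list that passed, and roX1, roX2 and msl-2. Trl, CCT1, CenG1A and other neighbours are named because a named summit lay in or near them.

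Overlap was taken with bedtools 2.31.1 at a minimum of 1 bp. Positions were shuffled 1000 times within arms, off unsequenced bases. Gene lists and motifs were compared by Fisher's exact test with Benjamini-Hochberg adjustment, X by an exact binomial test against length and Fisher's exact test on genes, and medians by a permutation test of 100000 resamples. All tests were two-sided. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used. On simulated data for the gene list test, 3 lists with a planted difference were each called in 20 of 20 runs over 13968 genes. Of 440 tests of coding lists without one, 6 were called. The planted lists had 93, 73 and 179 members and large differences, so these runs do not measure power for shorter lists. Genes were drawn independently, so neighbours that share a peak were not simulated. Random positions were called different from shuffles in 0 of 20 runs, and equal medians of 500 simulated signals in 1 of 20.

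Alternatives were the stronger 50% of the peaks, the strongest peaks of each replicate alone, promoter windows of 250 and 1000 bp, other overlap rules, 1 TSS per gene, other sequence windows and the dm3 lists. Overlapping peaks counted once, shuffles off repeats, all pooled peaks for the gene lists, TSS-centred motif windows and both windows for X genes were chosen after seeing the data.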

Results

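Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole adult male Drosophila melanogaster from a transgenic line in which tHMG1 (CG7045), an HMG-box protein named for its expression in testis, carried GFP at its C-terminus. An antibody against GFP recovered the bound DNA. The 2 biological replicates, numbered 1 and 3, formed 1 group, so the data addressed where in the genome the tagged protein was enriched, and no contrast between groups could be made. The values were peak lists with a signal for each peak. Read depth was unknown, so no counting error could be attached to a peak. Coordinates are those of build dm6, and peak signals are the authors' own values.

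The peaks that passed the authors' irreproducible discovery rate (IDR) procedure numbered 4574, with a median signal of 145.9 and a range from 90.3 to 2864. All were at most 807 bp long, with a median length of 444 bp. The strongest peak, at 3L 19590393 to 19590844, had its summit in intergenic sequence 96 bp from the transcription start site (TSS) of CG14100, with a signal of 2864 (1779 in replicate 1 and 1093 in replicate 3), and ranked first in both replicates. The second, at 2L 6612347 to 6613013, lay in an intron of CG11050 with a signal of 2648. The third, at 3L 14759259 to 14759790, lay in an intron of Trl, which encodes the GAGA factor, with a signal of 2023, and its nearest TSS was that of CG42507 at 1540 bp. The fourth, at X 2703664 to 2704099, lay 25 bp from the TSS of Ugalt, a UDP-galactose transporter, and had the highest signal on X, 2007. The other peaks among the 10 strongest were nearest to CG18428, DNAlig3, mRpL41, CG11309, CG16753 and Lk6, with signals from 1549 to 1864. Of the 10, 5 had their summit within 500 bp of a TSS. On chromosome 4 the strongest peak lay 46 bp from the TSS of RpS3A, with a signal of 264.1.

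Most IDR peaks were also among the strongest peaks of each replicate. Of the 4574 peaks, 4134 overlapped by at least 1 bp one of the 4574 strongest peaks of replicate 1, and 3897 one of those of replicate 3. Overlap in both was found for 3505 peaks (76.6%), against a mean of 1.76% and a highest value of 2.49% in 1000 shuffles within chromosome arms (permutation p = 0.0020, the smallest the shuffles could give, two-sided). The IDR peaks are the strongest rows of the pooled list, which was made from both replicates. An overlap far above the shuffles was therefore set by their construction. Their place on the list does not show that each single peak was reproducible. Between the replicates' own lists, 3481 of the 4574 strongest peaks of replicate 1 (76.1%) overlapped one of the 4574 strongest of replicate 3, a value with no test. The replicates' own lists differed in scale, with a median signal at these peaks of 85.9 in replicate 1 and 63.7 in replicate 3. Spearman's rho of the signals was 0.650 across the 4558 peaks with a value in both replicates. This correlation is across peaks, which are not independent replicates. The peaks were also chosen by a cut on the pooled signal, so rho does not describe agreement over all peaks of the replicates.

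Promoter positions were over-represented among the summits. Summits of 2649 peaks (57.9%) lay within 500 bp of an annotated TSS, against 13.7% of shuffled positions (permutation p = 0.0020, two-sided). The share was 56.9% among the strongest peaks of replicate 1 and 58.3% among those of replicate 3. It depended on the window: 46.2% of summits lay within 250 bp of a TSS (7.56% of shuffled positions) and 68.96% within 1000 bp (23.8%). Over all 30000 peaks of the pooled list, which include background, the share within 500 bp was 36.3%, and it was 32.4% in the 25426 below the IDR peaks. Introns outside promoters held 1493 summits (32.6%, against 39.3% of shuffled positions), and intergenic sequence held 307 (6.71%, against 27.4%). Coding exons held only 14 summits (0.306%, against 13.7%), and 3' UTRs held 39 (0.853%, against 4.33%). Each of these 5 departures had an adjusted permutation p of 0.0028 over 7 classes, whereas 5' UTRs and non-coding exons outside promoters did not pass (adjusted p = 0.454 for both).

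**Figure D1:**
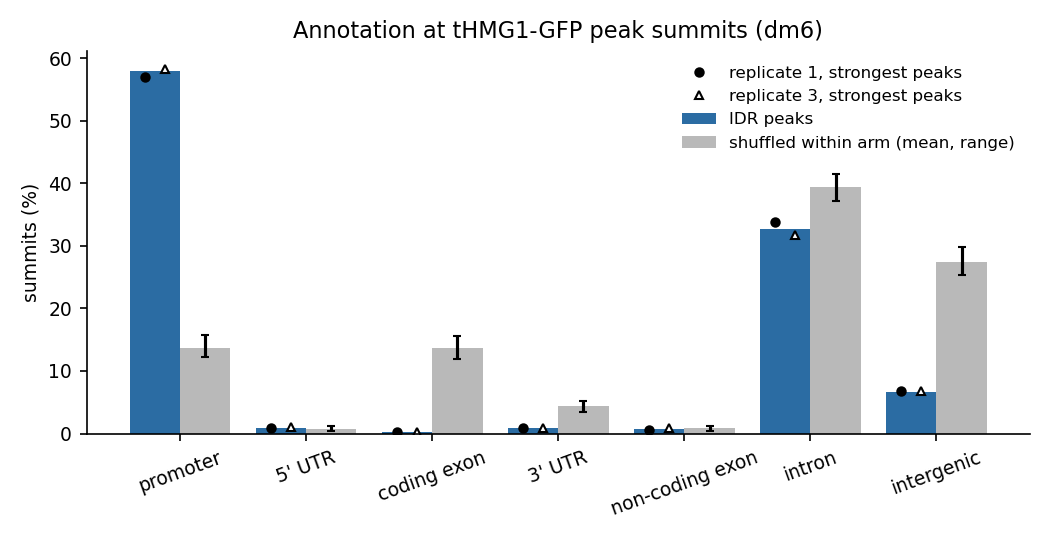
Percentage of summits (vertical axis) in each annotation class (horizontal axis), for the IDR peaks (blue bars) and for 1000 shuffles within arms (grey bars, mean, with lines from the lowest to the highest shuffle). Circles and triangles give the 4574 strongest peaks of replicates 1 and 3. Promoter summits stand at 57.9% against 13.6% of the positions in these shuffles. The separate shuffles that tested the promoter share alone gave 13.7%.

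Among the IDR peaks, those at promoters were slightly stronger than the others. Both groups were cut at the same lowest signal, so the comparison does not cover weaker peaks. The test below treats peaks as independent, although some overlap. The median signal was 151.6 at promoters and 138.8 elsewhere, a ratio of 1.09 (permutation test of the difference of medians, p = 1e-05, the smallest that 100000 resamples could give, two-sided). Among each replicate's own strongest peaks, a different set, the ratio was 1.12 in replicate 1 and 1.11 in replicate 3. The promoter share was 53.4% in the weakest 20% of the peaks and 66.4% in the strongest 20%.

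Peaks were sparser on X than on the large autosome arms. X held 602 of the 4562 peaks on X, 2L, 2R, 3L and 3R, or 13.2% (95% exact binomial interval 12.2% to 14.2%), although it makes up 17.8% of their length (exact binomial p = 6.12e-17, two-sided). The density was 25.6 peaks per Mb on X, and from 34.6 on 2R to 38.1 on 2L among the autosome arms. Of 2196 protein-coding genes on X, 307 (13.98%) had a bound promoter, against 2679 of 11669 (22.96%) on the 4 autosome arms. The odds ratio was 0.545 (95% interval 0.480 to 0.620, Fisher's exact p = 1.90e-22, two-sided), and it was 0.573 with the strongest peaks of replicate 1 and 0.514 with those of replicate 3. Chromosome 4 held 12 peaks, or 8.90 per Mb, and no list held a peak on Y. These tests treat peaks and genes as independent, although neighbouring genes can share a peak.

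**Figure D2:**
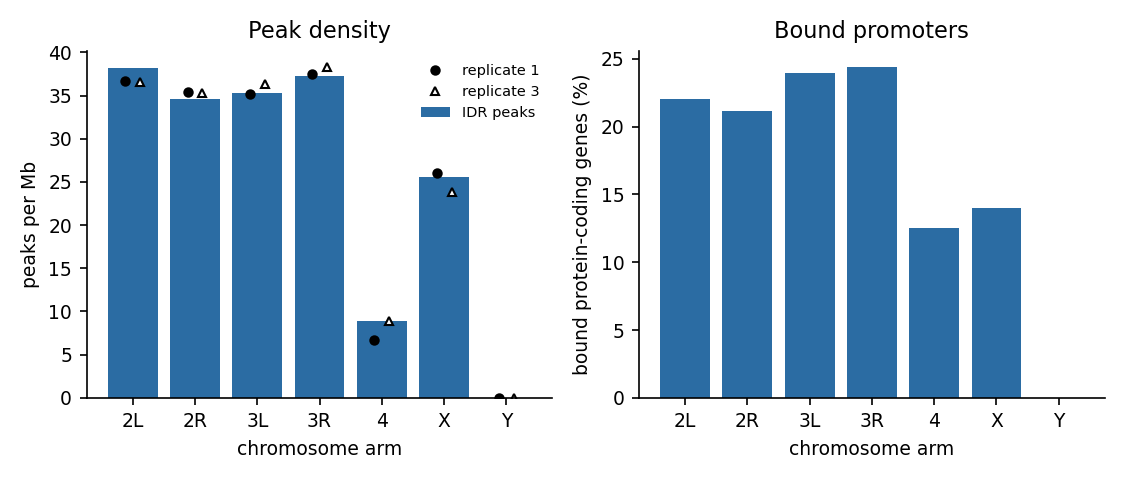
Left, peaks per Mb of each chromosome arm for the IDR peaks (bars) and the 4574 strongest peaks of replicate 1 (circles) and replicate 3 (triangles); right, percentage of protein-coding genes on each arm with a summit within 500 bp of a TSS. X has 25.6 peaks per Mb and 13.98% of its genes bound, below 2L, 2R, 3L and 3R on both plots.

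Across the genome 2996 of 13968 protein-coding genes (21.4%) had a bound promoter, and 11 of the 28 gene lists tested differed from the other genes by Fisher's exact test (two-sided, Benjamini-Hochberg over the lists). Genes for ribosomal proteins of the cytoplasm were bound most often among the large lists, 63 of 93 (67.7%, 95% exact interval 57.3% to 77.1%, adjusted p = 2.58e-20). RpS27, RpL7, RpL23A and RpL34b had the strongest of these peaks, with signals from 507 to 823. The RpS27 summit lay 19 bp from the TSS of that gene, in intergenic sequence at 3R 25247533, and the RpL7 summit lay in its 5' UTR at 2L 10201040. Genes for ribosomal proteins of the mitochondrion were bound in 32 of 73 cases (43.8%, adjusted exact p = 8.94e-05). Among them mRpL41 and mRpS10 had signals of 1726 and 1359, and mRpS23 and mRpL23 had 1219 and 1125. The mRpS23 summit was nearer to the TSS of CenG1A.

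Of 8 circadian clock genes, 6 were bound (Fisher's exact test, adjusted p = 0.00564). The light receptor cry had a peak signal of 1032, Pdp1 392.4, tim 380.9 and per 145.9. The cry summit, at 3R 19211915, was intergenic and 239 bp from the TSSs of both cry and a long non-coding RNA, the tim and Pdp1 summits were intronic, and the per peak had signals of 102.0 in replicate 1 and 23.3 in replicate 3. With the stronger 50% of the peaks alone, the clock share was 37.5% against 12.8% and the call was lost (Fisher's exact test, adjusted p = 0.201).

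Of the 5 testis lists, 1 differed from other genes. None of the 33 spermatid and sperm tail genes was bound (adjusted exact p = 0.00167). Chromatin came from whole males, so this share was not measured in testis cells alone. None of the 12 regulators of the spermatocyte transcription programme was bound either, but the list did not pass (adjusted exact p = 0.131). Among 9 sperm chromatin genes the only bound member was tHMG1 itself, and the list did not differ from other genes (Fisher's exact test, adjusted p = 0.748). Among 17 early germline genes 4 were bound (adjusted exact p = 0.771). These were nanos, a translational regulator of the germline (signal 189.8), stwl (146.5), spn-E, a helicase of the piRNA pathway (132.1), and bgcn (112.1). The nanos and stwl summits were each 348 bp from the TSS of the named gene and nearer to that of another, CG11779 and CG3919. None of the 10 Y-linked fertility genes was bound, and no list held a peak on Y. With the stronger 50% of the peaks the spermatid call was lost, while the share stayed at 0% against 12.9% of other genes (adjusted exact p = 0.0608). With all peaks of the pooled list, an alternative chosen after seeing the data, 3 testis lists passed: the spermatid genes (9.09% bound against 55.9%, adjusted exact p = 1.26e-07), the spermatocyte regulators (8.33%, adjusted exact p = 0.00208) and the Y-linked genes (0%, adjusted exact p = 0.000791). The Y-linked share could only be 0%, because no list held a peak on Y. Whether reads could be placed on Y was not known.

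Chemoreceptor genes were bound in 2 of 179 cases (adjusted exact p = 4.36e-15), Ir60e and Gr63a, and both summits were nearer to another gene's TSS. None of 120 cuticle protein genes was bound (adjusted exact p = 4.61e-12). None of the 21 sarcomere genes was bound (adjusted exact p = 0.0334), and 9 of 85 cytochrome P450 genes were (10.6%, adjusted exact p = 0.0325), with Cyp6u1, Cyp6t1, Cyp6v1 and Cyp317a1 the strongest at signals from 154.6 to 380.3. The Cyp6u1 summit, the strongest, lay in the 5' UTR of Ufsp1 and nearer to the TSS of that gene. The P450 call was lost under 7 of 8 alternatives and the sarcomere call under 5, and 2 sarcomere genes were bound among the strongest peaks of replicate 3. Male accessory gland, eggshell and yolk, and Jonah protease genes had no bound member, with an adjusted exact p of 0.0661 for each.

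None of 111 replication-dependent histone genes was bound (adjusted exact p = 2.01e-11). They lie in a repeated array of 124.7 kb at 2L 21416953 to 21541681, so the test counted copies at the same locus as 111 separate genes. Not one of the 30000 peaks of the pooled list fell there, against an average of 23.1 per 100 kb of 2L. Whether reads could be placed in this array was not known. Among non-coding genes, 26 of 290 tRNA genes (8.97%, adjusted exact p = 0.000105) and 18 of 269 snoRNA genes (6.69%, adjusted exact p = 7.36e-07) had a summit within 500 bp of an annotated TSS. The shares of all other genes were 18.0% and 18.1%. Whether the annotated start of a snoRNA gene is a promoter of its own was not examined, so the low snoRNA share is not shown to be one of promoters. Some neighbouring members shared a peak, such as tRNA:Arg-CCT-1-2 and tRNA:Arg-CCT-1-3 (signal 212.4), although the test treats genes as independent. The strongest tRNA peak, near tRNA:Tyr-GTA-1-8 (signal 707.7), lay in an intron and nearer to the TSS of CG8036. The strongest snoRNA peaks lay nearer to the TSSs of RpL14, RpL28 and Uhg4 (signals from 440.3 to 491.8), the last a snoRNA host gene. With a 1000 bp window the snoRNA share was 20.8% and the call was lost (adjusted exact p = 0.914). With all peaks of the pooled list, an alternative chosen after seeing the data, the tRNA share was 50.7% against 49.4% and the call was lost (adjusted exact p = 0.731).

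The other lists did not pass the test. Bound were 12 of 33 aminoacyl-tRNA synthetase genes (adjusted p = 0.0923), 11 of 32 proteasome genes (0.131), 6 of 16 heat shock genes (0.186), 22 of 84 oxidative phosphorylation genes (0.349), 5 of 40 patterning transcription factor genes (0.311), 2 of 15 neuronal genes (0.771), 1 of 16 phototransduction genes (0.294), none of 14 antimicrobial peptide genes (0.0923), none of 5 protein-coding dosage compensation genes (0.690) and 4 of 32 snRNA genes (0.720), with Fisher's exact test throughout. Of the dosage compensation loci named beforehand, roX1 had a promoter peak at X 3862271 to 3862714, in its exon, 68 bp from its TSS (signal 107.9). The nearest summits to the TSSs of roX2 and msl-2 were 2311 and 8773 bp away. With all peaks of the pooled list 16 lists passed in place of 11, among them the synthetase (78.8% bound), proteasome (81.3%), neuronal (86.7%) and antimicrobial peptide genes (0%), against 55.8% to 55.9% of other genes.

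**Figure D3:**
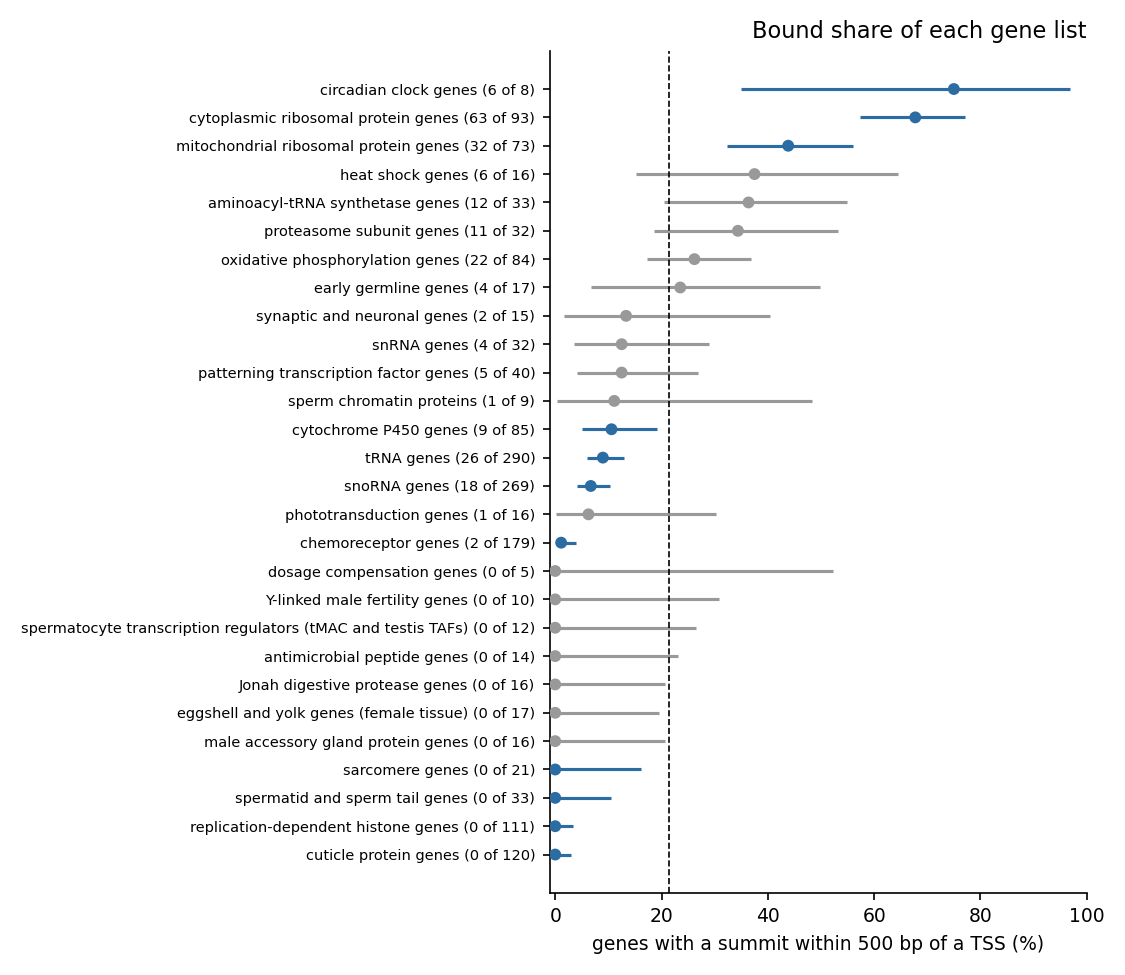
Percentage of the genes of each list with a summit within 500 bp of a TSS (horizontal axis), with 95% exact binomial intervals (lines); blue lists passed an adjusted p of 0.05, grey ones did not. The dashed line marks the share of all protein-coding genes, 21.4%; tRNA, snRNA and snoRNA genes were tested against all other genes.

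At the tagged gene, a peak of signal 131.6 (92.2 in replicate 1 and 49.2 in replicate 3) lay at 3R 22491197 to 22491640. Its summit was 410 bp upstream of the TSS of tHMG1 and in the 5' UTR of CCT1, a gene on the opposite strand whose TSS was 20 bp away. The homologue tHMG2 had no summit within 500 bp of its TSS, and the nearest to it was 1534 bp away. A peak of signal 243.9 lay beyond the 3' end of tHMG2, at 3R 22494552 to 22494995.

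**Figure D4:**
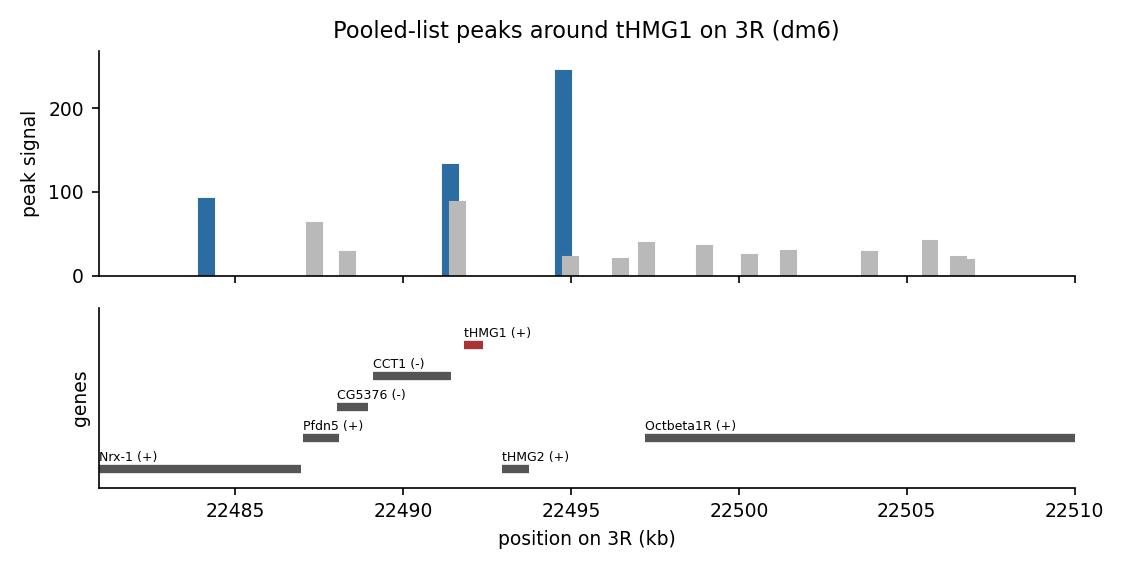
Signal of the pooled-list peaks (bars, to scale in position; blue, IDR peaks; grey, weaker peaks) and the genes with their strands (tHMG1 in red) along 3R, in kb of build dm6. The IDR peak nearest to tHMG1 has its summit in the 5' UTR of CCT1, 20 bp from the TSS of that gene.

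Sequence at the summits was poor in G and C. The 200 bp around IDR summits held 37.4% GC on average, against 42.2% at shuffled positions (permutation p = 0.0020, two-sided). The difference of -4.79 percentage points was -2.29 in 500 bp windows. Shuffles kept only the chromosome arm, so this difference was not separated from where summits lie in the annotation. Coding exons, for example, held 0.306% of summits and 13.7% of shuffled positions. Soft-masked repeat sequence covered 21.8% of the summits and 20.02% of shuffled positions (permutation p = 0.0040). This difference was not found in the strongest peaks of either replicate (20.6% and 20.9%, permutation p = 0.356 and 0.134), whereas the stronger 50% of the IDR peaks gave 25.1% (permutation p = 0.0020).

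Of 12 motifs, 8 differed between 2649 promoter summit windows and 10972 TSS windows of unbound genes (Fisher's exact test, two-sided, Benjamini-Hochberg). The GAGA repeat was found in 6.49% and 3.32% of windows (odds ratio 2.02, adjusted exact p = 1.60e-11) and the CA repeat in 4.76% and 2.61% (odds ratio 1.87, adjusted exact p = 1.69e-07). The SRY-type HMG-box site was found in 21.8% of both (odds ratio 1.00, adjusted exact p = 0.979). The other 6 calls were reversed or lost with windows centred on the TSS in both groups of genes, an alternative chosen after seeing the data: DRE went from an odds ratio of 0.719 to 1.58 and M1BP from 0.453 to 1.49. The TATA box went from 1.23 to 0.739, while the A tract, CTCF and Ohler 6 calls were lost. The E-box and the BEAF cluster, which had not passed, did so with odds ratios of 1.72 (from 0.879) and 2.17 (from 0.730). Of the 8 motifs, the GAGA and CA repeats kept both direction and call with these windows. Alternatives planned beforehand ended 5 calls. The CA repeat lost its call with the stronger 50% of the peaks (odds ratio 1.15, adjusted exact p = 0.474) and with 100 bp windows (1.39, adjusted exact p = 0.0808), CTCF with the stronger 50% (0.967, adjusted exact p = 1), the TATA box with 100 bp windows (1.08, adjusted exact p = 0.211) and DRE with promoter peaks defined at 250 bp (0.865, adjusted exact p = 0.207). The E-box passed under 3 of them, with odds ratios from 0.666 to 0.832. The GAGA repeat kept its call under all, with odds ratios from 1.40 to 2.24.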

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

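Tests of high transcription and of the strata of repeat sequence were chosen only after the results were seen; the other tests in this part were written before. The pooled dm3 list held 47 peaks on sequences named as heterochromatic or unplaced in that build. The comparisons were made in dm6, and where these sequences lie in dm6 was not examined. The strongest, on 3LHet, had a signal of 63.1, and the dm3 IDR list held none. Groups of 2 replicates are too small for a test of outlying samples.

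X promoters were bound less often than autosomal ones (odds ratio 0.545). The tables argue against repeat sequence: within 10 strata of the soft-masked share of promoter windows the Mantel-Haenszel odds ratio was 0.513 (95% interval 0.451 to 0.584). A first version of that test, on genes with no soft-masked base, had only 22 genes on X and an odds ratio of 0.630 (0.0758 to 5.23), an interval that holds 1, as written beforehand for repeats as the cause, but also 0.545, so it decides nothing. The single X of males stays open: with X peaks admitted at 50% of the threshold, the ratio of bound shares rose from 0.609 to 1.36 (1.27 to 1.46). A ratio above 1 was to count as fitting beforehand, but a lower threshold on X alone can only raise the ratio, and 1.36 lies above the 1 that equal binding at 50% of the signal would give, so the test decides nothing, and whether the authors' control already corrected for copy number is not known.

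Ribosomal protein promoters were bound in 67.7% of cases. High transcription as such stays open, because transcript levels were not measured. The test used 7 lists assumed to hold genes abundant in adult males, pooled after their counts were known. These were bound in 19.9% of cases (95% exact interval 14.6% to 26.1%), from 0% to 37.5% in single lists. Lists matched on the number of TSSs and on close neighbours were bound in 29.9% on average and at most 48.4% in 10000 draws. Lists matched on promoter GC were bound in 20.98% on average and at most 36.6%. Enrichment at promoters of broadly expressed genes whatever protein is tagged may also give this pattern. It may likewise give the low shares of spermatid, cuticle and chemoreceptor genes. Neither was tested, because no other tagged line or control was analysed here.

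The IDR peak assigned to tHMG1 lay 20 bp from the TSS of CCT1 and 410 bp from that of tHMG1, so it is consistent with a peak at the promoter of the neighbouring gene. A weaker pooled-list peak (signal 87.9, under the lowest IDR signal of 90.3) had its summit between the TSSs, 190 bp from that of CCT1 and 200 bp from that of tHMG1, and cannot be assigned to either gene. Extra copies of the tagged locus in the transgene cannot be told apart from other sources: 16 pooled-list peaks within 20 kb put tHMG1 at percentile 61.04 of coding genes, between the bounds set for either reading. The design has 1 group and so gives no biological contrast to set against these explanations, and no role of the tagged protein was tested.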

How the results depend on the processing

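No paired analysis was possible because the series has 1 group. The promoter share, the X deficit, the promoter to distal ratio and the GC difference kept their direction and call under every alternative run for each, including the added ones, although the promoter share itself went from 46.2% with a 250 bp window to 68.96% with 1000 bp. The alternatives leave out the admission of X peaks at 50% of the threshold, run as a test of a cause, which turned the ratio of bound shares to 1.36. Leaving out a replicate gave promoter shares from 56.9% to 58.3%, X shares from 12.3% to 13.4%, signal ratios from 1.11 to 1.12, GC differences from -5.20 to -3.60 percentage points, odds ratios for X genes from 0.514 to 0.573, and 9 to 13 lists past the threshold. Motifs past it numbered 8 either way. The repeat share lost its call without either replicate, at 20.6% to 20.9%. With the stronger 50% of the peaks, lists past the threshold fell from 11 to 7, all among the 11, and rho moved to 0.705; fewer bound genes per list leave less power in the first case, and the cause of the second was not tested. The overlap in both replicates was 57.7% with 50% reciprocal overlap and 97.6% with 2 times as many replicate peaks. The dm3 IDR list held 4322 peaks, and 4271 dm6 peaks remained when overlapping ones were counted once. Over single lists, 192 of 224 values kept their side of the threshold, 16 lost and 16 gained a call, and none reversed with a call in both directions. Shares did turn without a call in both settings. With all peaks of the pooled list, P450 genes went from 10.6% against 21.5% of other genes to 61.2% against 55.8%. Neuronal genes went from 13.3% against 21.5% to 86.7% against 55.8%. Over single motifs 68 of 84 values kept their side of the threshold, 8 lost and 5 gained a call, and 3 reversed, all with TSS-centred windows (chosen after seeing the data): DRE at 1.58, M1BP at 1.49 and the TATA box at 0.739. That alternative moves the windows of bound genes from the summit to the TSS and uses the same TSS windows of unbound genes. Read depth was unknown and limits weak peaks in a way that could not be measured.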

Other observations

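Families in this part were chosen after the results were seen, as groups of at least 12 protein-coding genes with a shared symbol and no member in the 28 lists. Of 31 families, 8 differed from other genes (Fisher's exact test, two-sided, Benjamini-Hochberg). Bound more often were Atg genes of autophagy (11 of 20, adjusted exact p = 0.0138), Usp ubiquitin proteases (9 of 15, adjusted exact p = 0.0138), Sec genes of protein secretion (10 of 19, adjusted exact p = 0.0170), Pex genes of peroxisomes (8 of 15, adjusted exact p = 0.0294) and MED genes of the Mediator complex (11 of 25, adjusted exact p = 0.0462). Bound less often were odorant binding protein genes (1 of 51, adjusted exact p = 0.00332), ppk channel genes (0 of 28, adjusted exact p = 0.0150) and Osi genes (0 of 25, adjusted exact p = 0.0271). Protein-coding genes known only by a CG number were bound in 898 of 6104 cases (14.7%), against 2098 of 7864 (26.7%) of the others.

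Against windows 1000 bp to either side of the same summits, 1358 of the 2034 8-base words present at 40 or more promoter summits were found more often at the summits and 5 less often (Fisher's exact test, two-sided, Benjamini-Hochberg). Among them were all 136 tested words made of A and T alone, and 19 of the 25 with the smallest p were of this kind, in line with the lower GC at summits. Of these ATTTAAAA came first, at 11.8% of summits and 4.19% of flanks (adjusted exact p = 2.42e-32). Of words with G or C, CAACACTG was found at 148 of 2649 promoter summits (5.59%) and in 0.755% of flanks (Fisher's exact test, adjusted p = 8.09e-35). The DRE word TATCGATA was found at 5.17% and 0.661% (adjusted exact p = 2.27e-33). At the 1925 other summits 353 of 1157 words were found more often, 101 of them made of A and T alone, and the leading words were CACTGAGA, at 2.81% against 0.519% (adjusted exact p = 3.16e-09), and TACACTGA, at 2.60% against 0.468% (adjusted exact p = 6.79e-09). Words were tested only if frequent at summits, which favours higher counts there, and the comparisons do not separate a word of the summit from a word of promoters in general. The test treated windows as independent and ignored that each summit was paired with its own flanks. Words that overlap can come from the same site, so the numbers of words are not numbers of separate sites.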
